A study of Homo sapiens with 2 samples.

How the data were processed

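RNA of NCI-H446 cells, an established small cell lung carcinoma line, stably carrying a control vector or an MTA1 overexpression plasmid, was hybridised to Affymetrix arrays, 1 array per group. The deposited values are log2 signals made by the authors with RMA, per the submitters' processing notes. The version of the software, the summarisation level, the annotation release and any further transformation of the values are not given in the sources used here. The values were used as deposited and were not normalised again in the reported setting. With 1 array per group the number of arrays limits the precision, and no spread between replicates exists.

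The 70523 deposited features comprised 67528 transcript clusters, 1437 exon regions, 28 junctions, 1344 numbered controls, 155 ERCC controls and 31 AFFX controls, and the control array lacked 1 value. Features were named through the probe table of the platform. There were 23781 probe sets with 1 gene symbol and 1543 with several, and 42204 transcript clusters were unnamed here. Probe sets with several symbols gave no gene name. Of those with 1 symbol, 21497 were matched by gene identifier to a RefSeq table of assembly GRCh38.p14 and took its current symbol, and 2284 kept the symbol of the probe table. No genome build is named for the array in the sources used here, so the RefSeq table served only for names, gene types, chromosomes and the order of neighbouring genes, and no coordinates are given. For 99.7% of 20518 named clusters the chromosome in the cluster identifier matched that of the table.

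Each of 22465 genes was represented by its brightest probe set with a single symbol. The floor was the median, over transcript clusters, of the mean of both arrays, a log2 signal of 3.62, and a gene was kept if the higher of its values reached it, which left 14451 genes. Genes with a log2 difference, MTA1 minus control, of at least 1 in size were counted as 2-fold higher or lower. Where 1 array lay below the floor, a named gene's fold was computed against the floor and is given as a lower bound.

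The samples were grouped by their labels. The reported settings, the gene lists, the rule for named genes and most alternative settings were chosen before the data were examined. The rule named MTA1, the 15 genes with the largest higher and the 15 with the largest lower difference whose probe sets at or above the floor had 1 sign, up to 4 members of each list by size of difference and up to 6 in lists that stood apart, and the spike-in controls. Uncharacterised loci, small RNA genes and antisense transcripts were skipped for naming and kept in the counts. MTA3, HDAC1, HDAC2, CHD4, CDH1, MYC, UCHL1, SYP, CHGA and NCAM1 were named in addition, after their values were seen.

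The 39 lists held 785 genes, of which 698 were measured and 584 were at or above the floor. They covered the NuRD complex, genes tied to MTA1, neuroendocrine and non-neuroendocrine small cell lung cancer genes, epithelial adhesion, mesenchymal genes, matrix proteases and their inhibitors, integrins and laminins, cell cycle phases, cyclins and CDK inhibitors, DNA repair, p53 targets, apoptosis, drug handling, NF-kB, interferon, antigen presentation, hypoxia, glycolysis, cholesterol synthesis, protein and heat stress, immediate early genes, the YAP, Wnt, Notch and TGF-beta pathways, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, histones, housekeeping genes, markers of other cell types, and cancer testis genes. A list's median difference was placed among the medians of 10000 random lists of the same size drawn from genes of the same signal in 20 bins, and a list outside their central 95% was said to stand apart. This percentile describes these arrays and is not a p-value. Genes of 1 list vary together, which random lists do not, so the percentiles are more extreme than independent evidence would make them.

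The steps were tested on simulated data over 14451 genes. Of simulated 2-fold genes 50.0% passed the 2-fold threshold, of 3-fold and 4-fold genes 100.0%, and of 1.5-fold genes 0.0%. Of simulated unshifted lists of 20 genes 4.5% stood apart. The simulated noise was symmetric, independent between genes and of the local spread of these arrays. These shares therefore follow largely from the settings. They check the steps and say nothing of differences between cultures or of genes that vary together. Alternatives changed the scaling, the floor, the probe set per gene, the fold threshold and the random lists. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1 for loess and quantile normalisation.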

Results

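Transcript levels were measured in NCI-H446, an established human small cell lung carcinoma line, in cells carrying a control vector and in cells stably transfected with a plasmid that overexpresses MTA1, a subunit of the NuRD histone deacetylase and chromatin remodelling complex. Each group was represented by 1 array. The comparison asked which transcripts differ when MTA1 is overexpressed. With 1 array per group there was no replicate check on any difference, no test could be run, and every difference below describes these 2 arrays. The deposited values were log2 signals. Their median was 3.67 on the control array and 3.68 on the MTA1 array, and they ranged from 1.83 to 19.93 and from 1.88 to 19.92. Values above 16, the log2 of the largest 16-bit scanner reading, occurred at 829 features, so the values hold a further transformation not given in the sources used here, and the fold sizes below depend on it. Across the 14451 genes at or above the signal floor of 3.62, the signals of the 2 arrays correlated with a Pearson r of 0.996, a value across genes, which are not independent replicates. The median difference, MTA1 minus control, was -0.013, and 96.8% of these genes differed by less than 1.5-fold.

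MTA1 itself was 5.71-fold higher on the MTA1 array, with a log2 signal of 7.31 in the control cells and 9.82 in the overexpressing cells. It was the third largest higher difference among genes. MTA1 lies on chromosome 14 and was measured by 1 transcript cluster. The other members of the NuRD complex were close to level. None of the 15 measured members, from MTA2 and MTA3 to HDAC1, HDAC2 and CHD4, reached 2-fold in either direction, and the largest difference was that of MTA2, at 11.18 in control and 10.93 in MTA1 cells. Their median difference was -0.011, at percentile 55.4 of 10000 random gene lists matched on signal. Which part of the MTA1 transcript the plasmid carries was not given in the sources used here, and endogenous and plasmid transcripts were not told apart.

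The signals of the 2 arrays were close for most genes, and 42 genes were at least 2-fold higher and 49 at least 2-fold lower on the MTA1 array. Among genes at least 2-fold apart, 30 of the higher and 33 of the lower were protein-coding. The largest higher difference of a gene was that of SNAI1, which encodes Snail, a transcriptional repressor of epithelial genes, at 5.89 in control and 8.55 in MTA1 cells, or 6.32-fold. SPINK6 and SPINK13, neighbouring genes on chromosome 5 for secreted Kazal-type protease inhibitors, were 6.18-fold and 4.91-fold higher. ANXA10, an annexin, was 4.76-fold higher and TLL1, a tolloid-like metalloprotease encoded on the same chromosome 4, was 2.66-fold higher. MUC16, the mucin that carries the CA125 antigen, went from 4.58 to 6.72 and was 4.40-fold higher. SLFN11, a nuclear protein known for blocking stalled replication forks under DNA damage, was 2.79-fold higher. The secreted Wnt antagonist DKK1 was 2.72-fold higher and the secreted guidance factor SEMA3F 2.66-fold higher. SFN, which encodes 14-3-3 sigma, stood at 12.08 in control and 13.42 in MTA1 cells, a 2.52-fold difference. CHAC1, a glutathione-degrading enzyme of the amino acid stress response, was 2.52-fold higher. AMTN, an enamel matrix protein gene, was 2.78-fold higher, and the Golgi mannosidase gene MAN1A1 was 2.51-fold higher. The immunoglobulin segment IGHD3-22 was below the floor on the control array and at least 2.94-fold higher on the MTA1 array.

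**Figure D1:**
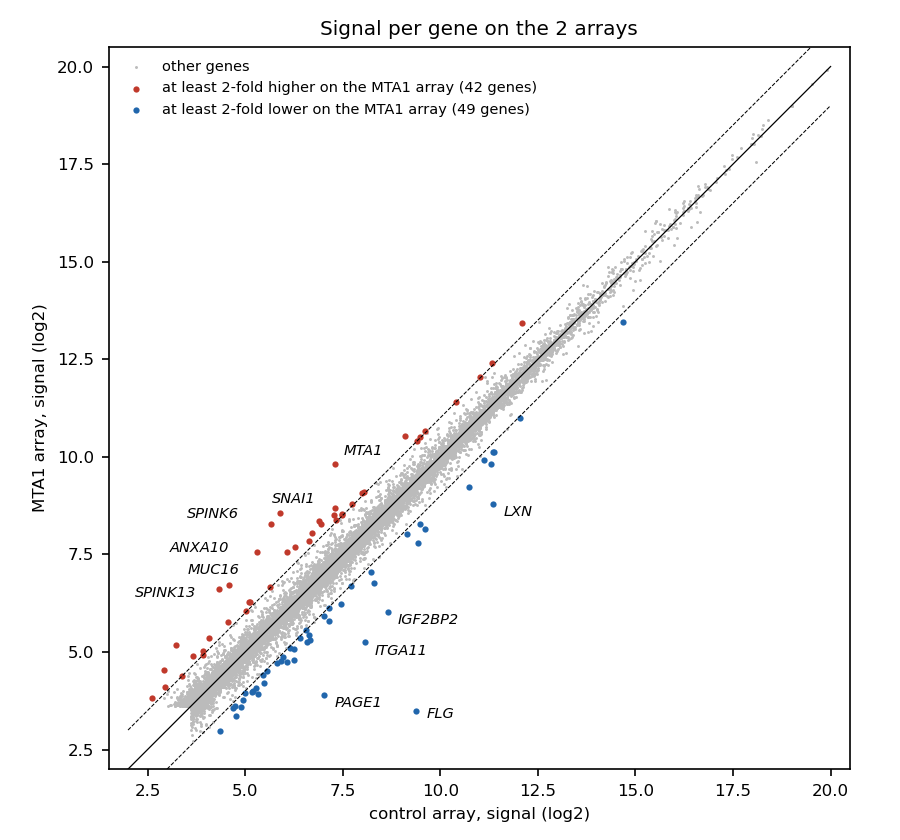
Signal per gene (log2) on the MTA1 array (y axis) against the control array (x axis), 1 array per group; each point is 1 of the 14451 genes at or above the floor, the solid line marks equal signal and the dashed lines 2-fold. Most genes lie along the diagonal, 42 genes lie at or above the upper dashed line and 49 at or below the lower one, with FLG the farthest from the diagonal.

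The largest difference of any gene was a lower one. FLG, which encodes the epidermal protein filaggrin, had a signal of 9.37 on the control array and 3.48, under the floor, on the MTA1 array, a difference of at least 54.1-fold. PAGE1, a cancer testis antigen gene on the X chromosome, was 8.76-fold lower, at 7.03 in control and 3.90 in MTA1 cells. ITGA11, a collagen-binding integrin subunit, was 7.02-fold lower, from 8.06 to 5.25. IGF2BP2, an RNA-binding protein gene, was 6.11-fold lower, and LXN, which encodes the carboxypeptidase inhibitor latexin, was 5.89-fold lower from a control signal of 11.35. BCAT1, the cytosolic branched-chain aminotransferase, was 3.10-fold lower, and the Notch ligand-like gene DNER 2.89-fold lower. The cytokine gene IL24 was 2.78-fold lower, from 11.30 to 9.82, and VGLL3, a cofactor of TEAD transcription factors, was 2.75-fold lower. The metalloreductase gene STEAP4 was 2.73-fold lower, the lectin gene CLEC2B 2.55-fold, the heparan sulfate sulfatase gene SULF2 2.48-fold and the lipid phosphatase gene PLPP4 2.43-fold lower. TNFSF10, which encodes the death ligand TRAIL, and the protocadherin gene PCDHB16 were under the floor on the MTA1 array and were at least 2.44-fold and 2.23-fold lower. Each of these 30 genes was measured by 1 transcript cluster. The difference varied between probe sets of the same gene with a pooled SD of 0.131 over 273 genes, and of 0.260 over the 157 genes left when copies on alternative haplotype contigs were removed. That spread covers differences between probe sets on the same RNA and not those between cultures. The numbered control features varied more, with an SD of the difference of 0.939. Of 1344 such features, 137 were at least 2-fold higher and 130 at least 2-fold lower on the MTA1 array. What they measure was not examined here, and they entered no count of genes.

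**Figure D2:**
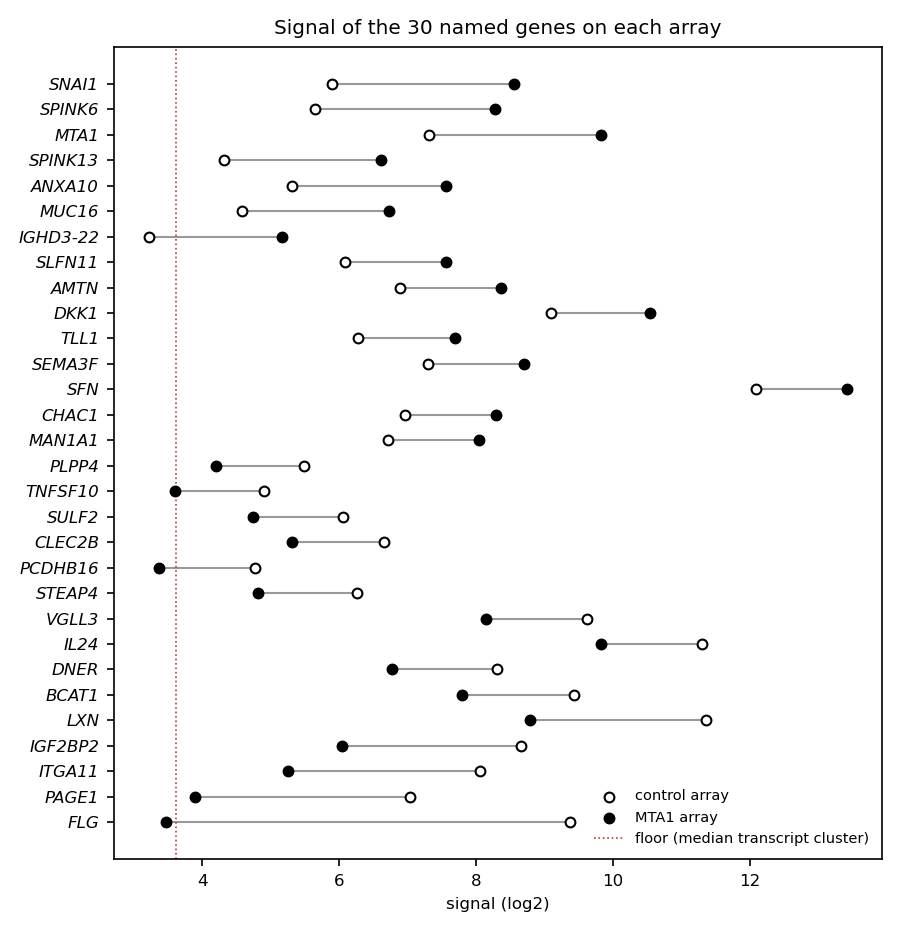
Signal (log2, x axis) of the 30 genes with the largest differences (y axis), on the control array (open circles) and the MTA1 array (filled circles), 1 array each with no error bars; the dotted line is the floor of 3.62. MTA1 stands at 7.31 and 9.82, and FLG goes from 9.37 to 3.48, under the floor.

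Of 39 gene lists fixed in advance, 16 had a median difference outside the central 95% of 10000 random lists matched on size and signal, 12 of them higher and 4 lower on the MTA1 array. If genes were independent, 1.95 lists would lie outside by chance, but the genes of a list are not independent and some genes are in several lists. List medians and counts cover the members at or above the floor. The differences behind these calls were small, and 33 of the 39 lists held no gene at least 2-fold lower or higher.

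The epithelial adhesion, mesenchymal, fibroblast, squamous, non-neuroendocrine, integrin and laminin, and matrix protease and inhibitor lists stood apart on the higher side. The epithelial adhesion list had a median difference of 0.22, at percentile 99.98 of random lists, with 10 genes above 0 and 5 below. Its largest differences were those of the desmosome gene DSP, 1.87-fold higher, and of the keratins KRT19 and KRT8, 1.81-fold and 1.66-fold higher. JUP, KRT7 and KRT18 were 1.24-fold, 1.23-fold and 1.20-fold higher. CDH1, which encodes E-cadherin, was below the floor on both arrays, at 3.09 and 3.13. The mesenchymal list was also higher, with a median of 0.13 at percentile 99.6, and 1 of its 18 genes at or above the floor, SNAI1, was past 2-fold. FAP was 1.39-fold and VIM 1.26-fold higher, FOXC2 stood at 3.40 and 3.70, near the floor, while the fibronectin gene FN1 was 1.49-fold lower and LOX 1.22-fold lower. Fibroblast markers share FAP and COL1A1, both at or above the floor, with that list. They had a median of 0.47 over only 5 genes at percentile 99.98. Among them MFAP5 was 2.08-fold and FBLN1 1.40-fold higher, whereas COL1A1, at 3.93 and 4.03, and DCN, at 3.89 and 3.53, were close to the floor on both arrays. Squamous epithelium markers had a median of 0.37 over 4 genes at percentile 99.8, and 6 of the 10 measured were below the floor on both arrays. Of the 4, TRIM29 was 1.34-fold higher and S100A2 was level at 5.28 and 5.27. KRT14, at 3.84 and 4.19, and SPRR1B, at 3.27 and 3.65, were close to the floor, and SPRR1B reached it only on the MTA1 array. FLG, the epidermal gene that was at least 54.1-fold lower, was not among the genes fixed for the squamous list. Genes of non-neuroendocrine small cell lung cancer were higher with a median of 0.22 at percentile 99.99, led by the integrin subunit ITGB4 at 1.73-fold and the annexin ANXA1 at 1.32-fold, followed by EPHA2, S100A10 and AXL at 1.26-fold, 1.26-fold and 1.24-fold. The integrin and laminin list had a median of 0.16 at percentile 99.8, with 10 genes above 0 and 6 below. In it ITGA6 was 1.42-fold, LAMA4 1.36-fold, ITGA3 1.32-fold and ITGA5 1.29-fold higher, and ITGA1 was 1.26-fold lower. ITGA11, the integrin gene that was 7.02-fold lower, was not among the genes fixed for this list. The list of matrix proteases and their inhibitors had a median of 0.13 at percentile 99.5, with 10 genes above 0 and 7 below. In it the protease inhibitor SERPINE2 was 2.03-fold, CTSL 1.29-fold, MMP14 and the inhibitor TIMP4 1.26-fold, ADAM9 1.22-fold and MMP1 1.20-fold higher. The proteases MMP2, ADAM17, ADAMTS1, PLAU, ADAM10 and CTSB were lower, by at most 1.12-fold, so the list does not show proteases higher as a group. Its median was 0.24 with the floor at percentile 75. Over all measured members, without the low-signal filter, the medians of the fibroblast, squamous, mesenchymal and integrin and laminin lists were 0.07, 0.11, 0.07 and 0.09 and none of these lists stood apart, while the epithelial adhesion list did with 0.13. Without the 3 members of largest difference the matrix protease and inhibitor list and the integrin and laminin list, at 0.04 and 0.05, and against untrimmed random lists also the epithelial adhesion list, at 0.11, did not stand apart, and the fibroblast and squamous lists had too few genes left for a value.

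The immediate early, unfolded protein and amino acid stress, Wnt, TGF-beta and cholesterol lists also stood apart on the higher side, while the heat shock, NF-kB, hypoxia and p53 target lists did not stand apart. The immediate early list stood furthest out of the larger lists, with a median of 0.29 above all 10000 random lists, and 14 of its 20 genes at or above the floor were above 0. IER3 was 1.91-fold higher, SPRY2 and DUSP5 1.65-fold and 1.62-fold, and JUNB, FOSB and JUND 1.47-fold, 1.42-fold and 1.35-fold higher. The unfolded protein and amino acid stress list had a median of 0.092 at percentile 99.5, with 15 genes above 0 and 11 below. CHAC1 led it, followed by VLDLR at 1.59-fold, PPP1R15A at 1.47-fold, SESN2 at 1.38-fold and HERPUD1 at 1.35-fold, and DDIT4 was 1.37-fold lower. Wnt target genes had a median of 0.16 over 10 genes at percentile 99.1, with DKK1 past 2-fold, BMP4 1.39-fold, CCND1 1.23-fold, CD44 1.18-fold and TCF7L2 1.17-fold higher, and MYC at 11.17 and 11.06. Of the 19 measured Wnt target genes 9 were below the floor on both arrays, AXIN2, LEF1, LGR5, RNF43 and SP5 among them. TGF-beta response genes had a median of 0.10 at percentile 99.3, with ID2 at 1.52-fold, CCN2 at 1.39-fold, BHLHE40 at 1.38-fold and SMAD3 at 1.27-fold, and TGFBR2 and SMAD6 1.26-fold and 1.25-fold lower. Cholesterol synthesis genes had a median of 0.094 at percentile 98.3, and 16 of 19 genes were above 0, among them MVD at 1.31-fold, INSIG1 at 1.19-fold, NSDHL at 1.17-fold and MSMO1 at 1.16-fold, while HMGCS1 and HSD17B7 were 1.26-fold and 1.25-fold lower. Without the 3 members of largest difference the unfolded protein and Wnt lists, both at 0.03, did not stand apart, and the Wnt list did not without the low-signal filter, at 0.05, or with the mean of all probe sets of a gene, at 0.07. The unfolded protein list had a median of 0.18 with the floor at percentile 75 and 0.14 with quantile normalisation repeated, and the cholesterol list 0.14 after loess. The TGF-beta list did not stand apart when only the list, and not the random lists, was trimmed. The bacterial hybridisation controls bioB, bioC, bioD and cre were higher on the MTA1 array too, by 0.23, 0.24, 0.23 and 0.28 on the log2 scale. These differences exceeded the medians of most lists on the higher side, and no setting scaled the arrays to spike-in controls. A constant shift to them would lower every list median and could turn small ones negative. It would not by itself move a list relative to random lists, which would shift alike.

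**Figure D3:**
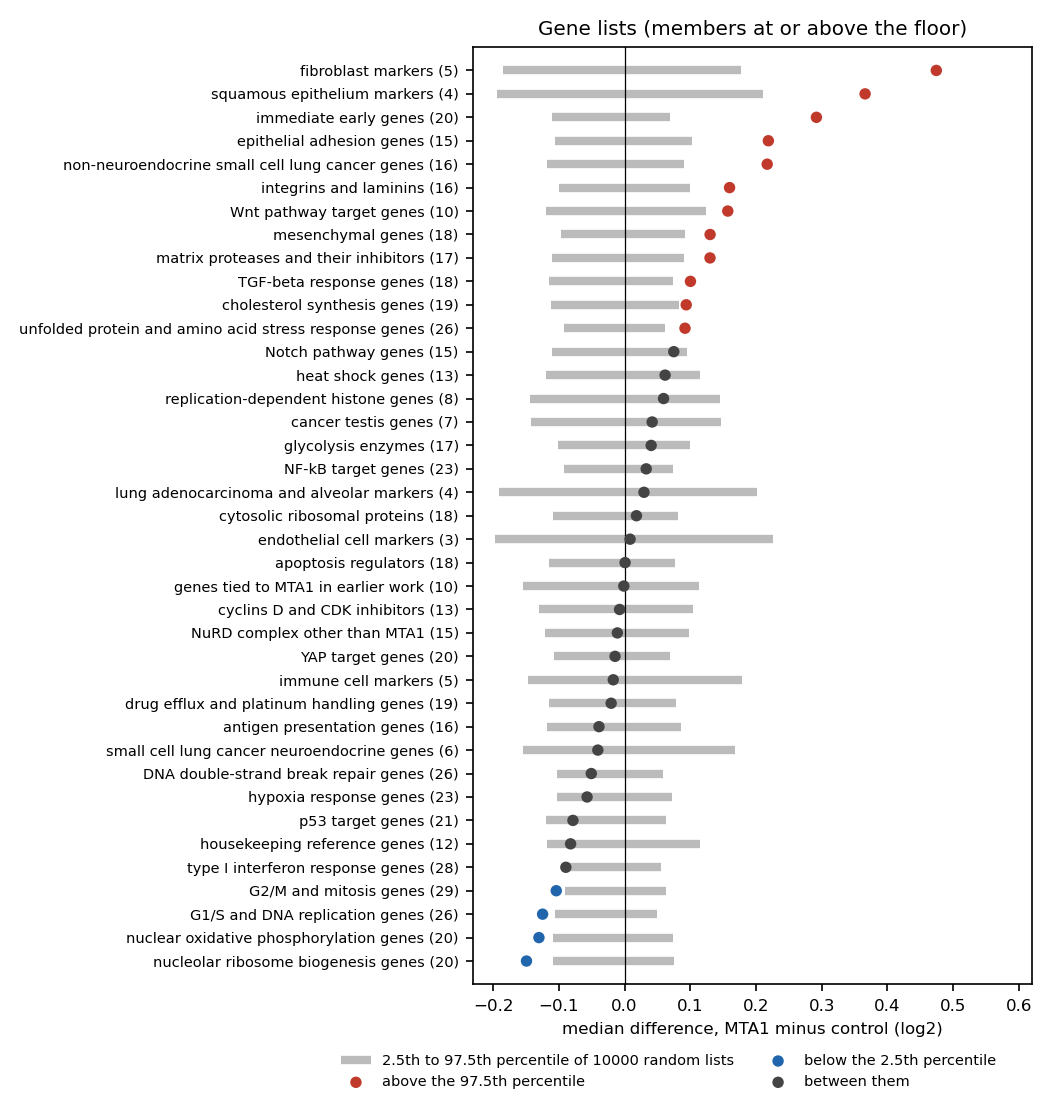
Median difference, MTA1 minus control (log2, x axis), of the 39 gene lists (y axis, number of genes at or above the floor in brackets); grey bars span the central 95% of 10000 random lists of the same size and signal and are not errors of the medians. The immediate early list stands at 0.29 and the nucleolar ribosome biogenesis list at -0.15, both beyond their grey bars.

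The 4 lists that stood apart on the lower side were those of G1/S and DNA replication, G2/M and mitosis, nucleolar ribosome biogenesis and nuclear oxidative phosphorylation. In the G1/S and DNA replication list 22 of 26 genes were below 0 and the median was -0.12, at percentile 0.71. MCM10, a replication initiation factor, was 1.54-fold lower, the GINS subunit GINS1 1.46-fold, E2F2 1.40-fold, E2F8 1.31-fold, POLA1 1.28-fold and CDC6 1.25-fold lower. In the G2/M and mitosis list 22 of 29 genes were below 0 and the median was -0.10, at percentile 1.1, with HMMR and PTTG1 1.25-fold and 1.24-fold lower and KIF11, NUSAP1, KIF20A and BUB1 1.20-fold, 1.20-fold, 1.19-fold and 1.15-fold lower. Nucleolar ribosome biogenesis genes were below 0 in 19 of 20 cases, with a median of -0.15 at percentile 0.26. NOLC1 was 1.34-fold, the rRNA methyltransferase FBL 1.32-fold, PNO1 1.23-fold, WDR43 1.18-fold, BOP1 1.17-fold and NOP16 1.14-fold lower. Nuclear genes of oxidative phosphorylation were below 0 in 18 of 20 cases, with a median of -0.13 at percentile 0.63, and ATP5MC1, UQCRB, NDUFB5, COX5B, CYCS and COX5A were 1.19-fold, 1.17-fold, 1.15-fold, 1.15-fold, 1.14-fold and 1.12-fold lower. No gene of these 4 lists reached 2-fold. The oxidative phosphorylation list did not stand apart without its 3 members of largest difference when random lists kept theirs. Cytosolic ribosomal proteins did not stand apart, at percentile 77.7, with RPS15 at 16.78 and 16.99, RPL30 1.15-fold higher, RPL27 1.12-fold lower and RPL8 1.11-fold higher.

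The remaining lists lay within the range of random lists. Genes tied to MTA1 in earlier work were at percentile 64.6 over 10 genes, with SMAD7 1.24-fold and CDKN1A 1.23-fold higher and BRCA1 and VEGFA 1.20-fold and 1.19-fold lower. DNA double-strand break repair genes were at percentile 25.0, although BLM was 1.45-fold and XRCC2, EXO1 and MRE11 1.28-fold, 1.26-fold and 1.25-fold lower. In the p53 target list, at percentile 13.5, ZMAT3 and MDM2 were 1.61-fold and 1.46-fold lower, EDA2R stood at 7.66 and 7.08, and PMAIP1 was 1.56-fold higher. Type I interferon response genes were at percentile 3.17, with IFI27 1.82-fold higher and IFIT1, OASL and OAS2 1.58-fold, 1.40-fold and 1.36-fold lower. This list stood apart on the lower side when both arrays had to reach the floor, and with random lists left unmatched or drawn from protein-coding genes. The hypoxia list was at percentile 17.1, with ADM 1.90-fold higher and SLC2A3, DDIT4 and EGLN3 1.53-fold, 1.37-fold and 1.36-fold lower. The drug efflux and platinum handling list was at percentile 49.9, with ABCG2, GSTP1, ABCC4 and ERCC4 1.61-fold, 1.31-fold, 1.23-fold and 1.22-fold lower. YAP target genes were at percentile 55.7, with CCN1, GADD45B and CCN2 1.69-fold, 1.68-fold and 1.39-fold higher and NT5E at 14.30 and 14.87. NF-kB target genes were at percentile 85.7, with TNFAIP3 1.36-fold higher and CSF1, IL6 and CXCL10 1.32-fold, 1.31-fold and 1.30-fold lower. Antigen presentation genes were at percentile 32.3, with ERAP1 1.53-fold and PSMB9 1.34-fold lower. The Notch list was at percentile 93.6 with NOTCH1 1.18-fold higher and DLL4 near the floor at 3.45 and 3.72, and the apoptosis list at percentile 67.7 with TNFRSF10B 1.21-fold and BCL2L11 1.19-fold lower. Cyclins D and CDK inhibitors were at percentile 57.4, heat shock genes at 87.9, glycolysis enzymes at 81.8 and replication-dependent histones at 83.5. In these lists CCND1 was 1.23-fold higher, HSPA4L 1.18-fold lower, ALDOC 1.35-fold lower and H2BC21 1.37-fold higher, and the histone list stood apart without its 3 members of largest difference when random lists were trimmed alike. Housekeeping reference genes were at percentile 9.03, with TFRC 1.24-fold and GUSB 1.13-fold lower, and with quantile normalisation repeated this list also stood outside the central 95%. Median and mean differed in sign for the lists of genes tied to MTA1, cyclins D and CDK inhibitors, apoptosis, NF-kB, glycolysis, YAP and immune cell markers, whose members went both ways. The median also changed sign with quantile normalisation for the hypoxia, cyclin and YAP lists, with loess for the YAP list, without the low-signal filter for the histone list, and without the 3 largest members for the drug handling and housekeeping lists. Other small medians crossed over too. That of genes tied to MTA1 went from -0.00 to 0.02 without the low-signal filter. With median centring the apoptosis median went from 0.00 to -0.02 and that of cytosolic ribosomal proteins from 0.02 to -0.00.

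Of the 20 measured small cell lung cancer neuroendocrine genes 14 were below the floor on both arrays. Those above it included ENO2, at 8.89 in control and 9.13 in MTA1 cells, and UCHL1, at 5.30 and 5.21. INSM1 stood at 4.06 and 4.21, and SYP, CHGA and NCAM1 were below the floor. The 6 genes at or above the floor were at percentile 24.9 with a median of -0.04, which turned to 0.05 over all measured members and to 0.08 when both arrays had to reach the floor, so the list has no settled direction. Most measured markers of other cell types were also below the floor. Of the immune cell markers 10 of 15 were below the floor, and of the endothelial markers 9 of 12. For the alveolar and lung adenocarcinoma markers it was 11 of 15. The median differences of the members at or above the floor were -0.017, 0.0084 and 0.030, all inside the central 95% of random lists. None of the 3 has a settled sign, since the immune median was 0.04 over all measured members, the endothelial one -0.01 with median centring, and the alveolar one -0.05 with median centring, -0.04 with loess and -0.03 with quantile normalisation or with both arrays at the floor. Among them CD68 stood at 11.26 and 11.19 and MUC1 at 8.66 and 9.15. Cancer testis genes were at percentile 76.7. Here the median was 0.042 and the mean -0.46, because PAGE1 was far lower on the MTA1 array while MAGEA1, at 10.25 and 10.36, and PRAME, at 6.55 and 6.61, were level.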

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

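The tests of unnamed features were chosen after their values were seen. Transcript clusters without a gene name here entered no count of genes, and 122 of the 19275 at or above the floor were at least 2-fold higher on the MTA1 array, while 199 were at least 2-fold lower. The cluster TC15001909.hg.1 stood at 2.86 on the control array and 7.35 on the MTA1 array, a log2 difference of 4.49. The cluster TC15000503.hg.1 stood at 2.86 and 6.95, a difference of 4.09. Both differences exceeded the 2.66 of SNAI1, the largest higher difference of a named gene. In the lower direction TC01005829.hg.1 differed by -6.47 from 10.47 on the control array, and TC01005828.hg.1 stood at 9.21 and 2.85. What these clusters measure was not analysed here, and no biological explanation was tested.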

How the results depend on the processing

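The tests without the 3 largest members of a list, with random lists trimmed alike, without haplotype contigs, with protein-coding genes only, with the floor over all feature kinds and with loess against unmatched random lists were chosen after the data were seen. The MTA1 difference ranged from 2.49 to 2.56 over median centring, loess and repeated quantile normalisation. The mean of probe sets could not change it, since MTA1 has 1 probe set. Over other scalings, floors and probe set rules, 33 to 49 genes were at least 2-fold higher and 35 to 53 lower, and protein-coding genes alone gave 30 and 33. Which direction held more genes depended on the scaling, with 49 higher and 44 lower after quantile normalisation. The fold threshold moved the counts most: 210 genes were at least 1.5-fold higher and 252 lower, and 8 and 6 passed 3-fold. Beyond 4 local SD and 1.5-fold there were 161 higher and 157 lower, by construction a looser threshold. Between 26 and 30 of the 30 named genes were shared by the top genes of each setting. Without haplotype contigs the spread between probe sets was 0.260, because copies of a gene on those contigs were removed.

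Between 11 and 17 lists stood apart in the other settings, but only 7 without the 3 members of largest difference when random lists kept theirs. The non-neuroendocrine, G1/S, G2/M, cholesterol, immediate early and ribosome biogenesis lists stood apart in all 12 alternative settings. The epithelial adhesion, TGF-beta and oxidative phosphorylation lists were lost only in the setting with 7 lists. The fibroblast and squamous lists had too few genes for a value without their 3 largest members, as had the squamous list with the stricter floor. No list that stood apart and no named gene changed sign. No paired analysis was possible because each group has 1 array and the labels give no replicate numbers. For the same reason no array could be left out and no other split of the samples exists. A setting without ambiguous probe set suffixes was not run, since the array has none. Differences of genes near the floor of 3.62 rest on a signal close to background.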

Other observations

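Of the tests here, those of chance order, of a few large members and of loess with unmatched random lists were chosen after the results were seen. Marker genes were set only against the floor, in a comparison chosen after the values were seen. Of the 17 measured non-neuroendocrine small cell lung cancer genes 1 was below the floor on both arrays, and of the 20 measured neuroendocrine genes 14 were. Of the 21 measured epithelial adhesion genes 6 were below it, CDH1 among them.

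Gene types differed in how often they passed 2-fold. Of 663 small RNA genes at or above the floor 2.71% did, with 8 higher and 10 lower, against 0.541% of 11643 protein-coding genes. The shares were 0.810% of 494 lncRNA genes and 0.363% of 1651 other genes. Small RNA genes also had a wider spread of differences than protein-coding genes, with an SD of 0.387 against 0.237. Their median signal was lower, at 5.16 against 7.15. Whether their larger share reflects more than spread and signal was not tested. The poly-A spike-ins were higher on the MTA1 array as well, lys by 0.53, phe by 0.17, dap by 0.26 and thr by 0.84.

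Neighbouring protein-coding genes differed between the arrays in the same direction more than shuffled orders did. The rank correlation of adjacent genes was 0.124 over 11619 pairs, above the highest of 1000 shuffled orders, 0.031, which argues against chance order. Without overlapping genes and shared name stems it was 0.108, and after removal of trends with gene span and signal 0.119, so neither accounts for all of it. For segments of differing DNA copy number, genes 20 places apart correlated at 0.032, inside the shuffled range, which had been set as the bound against them, but that range is too loose a bound, since the value lies beyond the central 95% of shuffles, -0.018 to 0.019. Genes 5 places apart, for which no bound had been set in advance, correlated at 0.045, above the highest of 1000 shuffled orders, 0.023. Overlaps, shared name stems and trends with span and signal were not removed at 5 places, so the pattern may reach beyond immediate neighbours but this is unsettled. The shuffled orders also mixed all chromosomes, whose median differences ran from -0.075 on chromosome 13 to 0.031 on chromosome 4. Copy number therefore may contribute and stays open, as do GC content, not tested here, and shared regulation under MTA1.

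The 16 lists that stood apart were a second pattern. Random lists matched on signal carry any signal-dependent trend themselves, so such a trend could hardly set a list apart from them. With the trend removed by loess and the lists set against unmatched random lists, 0 of the 16 were lost. These lists had already been picked against matched random lists, so few losses were likely, and this second check adds little. For a few members with large differences, leaving out the 3 largest of each list while random lists kept theirs lost 7 of the 14 that still had a value, which met the bound of losing at least as many lists as were kept, and this first form favoured that explanation. A second form, adopted after that result was seen, trimmed random lists alike and lost 4 of 14, under the bound, so the forms differ in verdict and a few large members may account for part or much of the pattern. A different growth state of the culture could give lower cell cycle and ribosome biogenesis lists, and with 1 array per group it cannot be told apart from an effect of MTA1.

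SPINK6 and SPINK13, adjacent on chromosome 5, were both among the largest higher differences, while the 10 genes around them had a median of -0.02 and 0 past 2-fold. TLL1 and ANXA10 on chromosome 4 have SPOCK3 between them, with a difference of -0.10, and the median of the 10 genes around was -0.04.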
